A study of Danio rerio with 6 samples.

How the data were processed

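Tumour tissue of 6 fish was profiled, 3 SRBCT from fish with the EWS-FLI1 transgene and 3 MPNST from fish whose genotype label names no transgene. Per the labels' protocols, total RNA was extracted from each tumour, and 2.5 micrograms were copied to cDNA from an oligo(dT) primer and amplified to biotin-labelled cRNA. The cRNA was hybridized to zebrafish Affymetrix arrays, on which each transcript is read by several short probes that together form a probe set.

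The deposited values are expression values on a log2 scale, with 1 value per probe set and array. The submitters' processing notes name RMA, the affy package and R 2.2.0. RMA subtracts background, quantile-normalizes the arrays together and combines the probes of a probe set, and its output is log2. Base 2 is not written in the file and was taken from RMA and from the range of the values, 1.86 to 13.88 with 2 decimals. RMA draws dim values together, so differences between dim probe sets are understated, and a low value does not show that a transcript was absent. Any filter on arrays or probe sets is not given in the sources used here. Scanner files were not analysed here.

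The table has 15617 probe sets, of which 115 AFFX control probe sets were left out of the tests and 15502 were tested. Gene names came from the platform annotation of 2016, with symbols updated through Entrez identifiers to a RefSeq gene table of the GRCz12tu assembly. Of the tested probe sets 10795 have 1 gene symbol, 135 several and 4572 none here. The symbol of 1 probe set was updated, and for 84 the identifier was not found and the older symbol was kept. No gene was named from a probe set with several symbols. In this way 8793 genes were measured, 1539 of them by more than 1 probe set, and the probe set with the highest mean over the 6 arrays stood for the gene. No genome was used and no positions are given.

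The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) in a 2-group design over all 6 arrays without covariates. Probe sets with a Benjamini-Hochberg adjusted p under 0.05 were called changed, with no minimum fold. The 31 gene lists were written from textbook knowledge before the data were examined, as were the tests and the alternatives except where the closing section says otherwise. A list was tested with limma's camera at a preset inter-gene correlation of 0.01, with adjustment over the lists. Camera with an estimated correlation and fry were alternatives. With the estimated correlation 0 of the 31 lists passed, and with fry 2 did. The named genes are the up to 12 largest rises and 12 largest falls among called genes with separated groups and names that are not of the clone type. Added to these are up to 4 called members of each list, or otherwise the 2 members with the smallest p as values, and a few genes fixed for their link to the tumours. The text names a part of these.

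RNA integrity was compared through the 3' and 5' control probe sets with an exact permutation test. The methods were tested on simulated data of the same size: with the real spread of each probe set, 7.46% of changes of 1 log2 unit, 50.7% of changes of 2 and 89.4% of changes of 4 were recovered among 200 simulated changes, with 6 false calls. Precision is limited by the number of arrays. The alternatives were median centring, a second quantile normalization, cyclic loess, leaving out the dimmer probe sets, a trended and robust variance model, array weights, the replicate number as a block, leaving out each array in turn, a minimum log2 difference of 1, no moderation and the mean of a gene's probe sets. All columns of the table belong to these 6 samples. The same replicate number in both groups marks different fish, since the groups differ in genotype. The limma p-values of single probe sets measure the spread between the tumours of a group. Camera at the preset correlation compares a list's members with the other genes. It allows little for members that vary together between tumours, where the estimated correlation was 0.681 for intestine and pancreas markers.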

Results

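Gene expression was measured in 6 tumours of zebrafish, each hybridized to its own Affymetrix zebrafish array. The small round blue cell tumours (SRBCT, 3 arrays) arose in fish that carried the human EWS-FLI1 fusion gene under a heat shock promoter. The labels describe these tumours as resembling Ewing sarcoma, a human tumour of bone and soft tissue that is driven by a fusion of EWSR1 with an ETS gene such as FLI1. The malignant peripheral nerve sheath tumours (MPNST, 3 arrays) arose in fish whose genotype label names no transgene, and all 6 fish were homozygous for the same p53 mutation. The series asks what distinguishes the transgene-driven tumours from another tumour type of the same genetic background. The titles call the replicates biological, and each array gave 1 value for 15502 tested probe sets. The number of arrays, 3 in each group, limits the precision of every comparison. All differences are SRBCT minus MPNST on the log2 scale, so a positive value is higher in SRBCT, and errors given as SD are over n = 3 arrays.

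The MPNST arrays resembled each other more than the SRBCT arrays did. Correlations across probe sets were between 0.938 and 0.968 within MPNST. SRBCT 1 and SRBCT 2 correlated at 0.939, whereas SRBCT 3 correlated at 0.892 and 0.864 with them and at 0.875, 0.91 and 0.916 with the MPNST arrays. No pair of arrays was a duplicate, the smallest median absolute difference within a group being 0.23 log2 units. The first principal component held 52% of the variance, and SRBCT 3 lay between the other SRBCT arrays and the MPNST arrays on it. The 3' minus 5' signal of the GAPDH control probe sets, a sign of RNA integrity, was 0.64 ± 0.22 (SD, n = 3) in SRBCT and 1.06 ± 0.035 in MPNST. The difference of -0.42 had an exact two-sided permutation p of 0.1, the smallest that 3 arrays against 3 can give. The same measure for the muscle actin control had the opposite sign, a difference of 1.59 with an exact permutation p of 0.1. It was 0.74 ± 0.82 in SRBCT, with SRBCT 3 at -0.21, and -0.85 ± 0.17 in MPNST, where the 3' signal lay below the 5' signal.

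**Figure D1:**
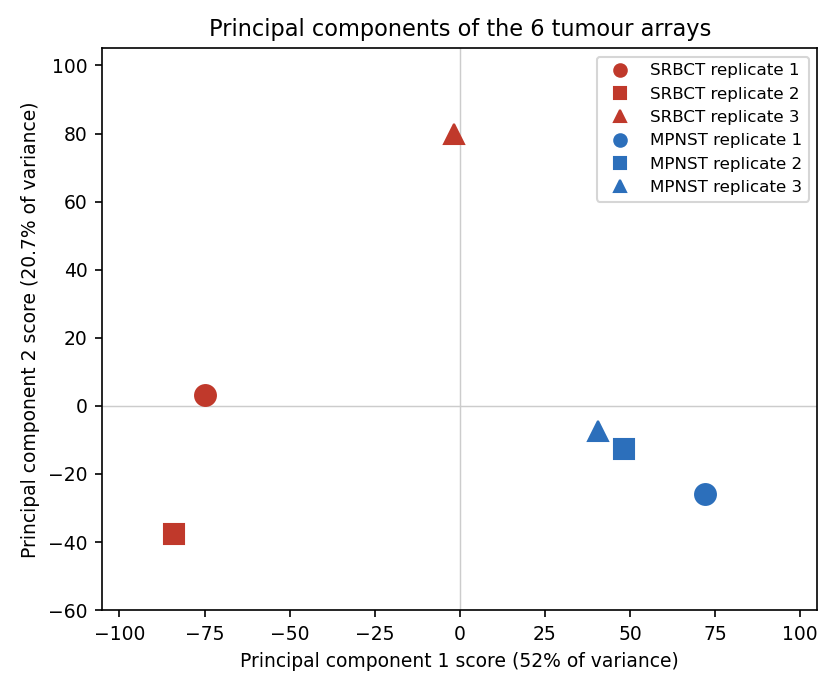
Scores of the 6 arrays on the first (x axis, 52% of the variance) and second (y axis, 20.7%) principal components of the log2 values, 1 point per array, in units of the score. SRBCT 3, at -1.8 on the first component, lies between SRBCT 1 and 2 (-74.9 and -84) and the MPNST arrays (40.7 to 71.9), and at 79.9 on the second it lies above the 5 others.

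Several of the 12 largest falls among called genes were oocyte and egg coat transcripts, which were high on the 3 MPNST arrays and much lower on the 3 SRBCT arrays. zp3.1, an egg coat (zona pellucida) glycoprotein gene, was 68.6-fold lower in SRBCT (log2 difference -6.10, SE 0.75, adjusted p 0.0295), with means of 5.71 ± 1.40 and 11.81 ± 0.74. The name of this probe set marks probes that may cross-hybridize. The other zp3.1 probe set differed by -5.05 (adjusted p 0.0333). The egg coat genes zp3f.1 (-4.94), zp3a.1 (-5.14), zp3a.2 (-4.91) and zpax4 (-4.98) fell by similar amounts. Of 17 zona pellucida family probe sets 11 fell, and 6 did not pass, for zp2l2 (-1.17), zp3b (-3.68), zp3c (-4.40), zp3d.1 (-1.39), zp3d.2 (-1.74) and zpd (-0.95). Falls were also found for zar1 (-4.47) and zar1l (-4.95), which encode maternal RNA-binding factors, and for btg4 (-4.82), which acts in the decay of maternal mRNA. The maternal linker histone gene h1m (-4.38) fell too. In all, 140 of 15502 probe sets changed in limma's moderated test with Benjamini-Hochberg adjustment, 126 of them lower and 14 higher in SRBCT. They represented 69 genes that fell and 8 that rose among 8793 genes.

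Other large falls were found in gtf3ab, a form of the 5S RNA gene transcription factor TFIIIA (-5.45, SE 0.45, adjusted p 0.00784), tmsb5 of the beta-thymosin family (-6.31, SE 0.47, adjusted p 0.00555) and sinup (-5.72, SE 0.31, adjusted p 0.00296). qdprb.4 (-5.19), the chitinase gene chia.4 (-5.17) and the LC3 family gene map1lc3c (-5.14) completed the 12 largest falls together with mpv17, a mitochondrial membrane protein gene (-6.51). The probe sets of mpv17 disagreed, 3 of 4 being lower in SRBCT, so its change is uncertain. Whether these genes belong with the oocyte transcripts was not tested. gtf3ab was at 10.36 on MPNST 1 against 9.01 and 8.87 on MPNST 2 and 3, and map1lc3c at 11.89 against 10.27 and 10.13. zar1 was at 10.66 against 9.09 and 8.56, whereas tmsb5 differed less, at 10.69 against 9.83 and 10.23. tmsb5 and sinup stayed past the threshold in each of the 6 fits that left out 1 array, and zp3.1 in 2 of them. Among all probe sets, 3498 had the 3 arrays of one group beyond the 3 of the other (22.6%, against 10% by chance). Of these, 2050 were higher in SRBCT.

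Few genes rose in SRBCT. The 6 with a gene name of the usual kind were dhrs12la (2.54, SE 0.36, 5.82-fold, adjusted p 0.046), pkp3a (2.40, SE 0.29, adjusted p 0.0271), olfm2a (2.36, adjusted p 0.0487), gng7 (1.88, adjusted p 0.0388), wls (1.74, adjusted p 0.043) and ahsa1a (1.58, adjusted p 0.0422). pkp3a encodes the desmosomal protein plakophilin 3, gng7 a G protein gamma subunit, wls the carrier that brings Wnt ligands to the cell surface, and ahsa1a an activator of the chaperone Hsp90. All 6 passed in the fit without SRBCT 3. dhrs12la, pkp3a and olfm2a passed in 1 more of the 6 fits that left out 1 array, and gng7, wls and ahsa1a in no other. The other risen genes have clone-type names. One of these, si:dkeyp-1h4.9, was chosen after its values were seen: it had the largest rise, with 11.23 ± 0.64 in SRBCT and 4.84 ± 0.55 in MPNST (log2 difference 6.39, adjusted p 0.00424).

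The number of changed probe sets depended on single arrays. It was 1140 without SRBCT 3 (569 higher, 571 lower), 26 without SRBCT 1, 38 without MPNST 2 and 57 without MPNST 3, and without SRBCT 2 it was 109, of which 37 were higher and 72 lower. The fit without SRBCT 3 kept all 140, and 88 of the 140 probe sets have exactly 1 gene symbol.

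**Figure D2:**
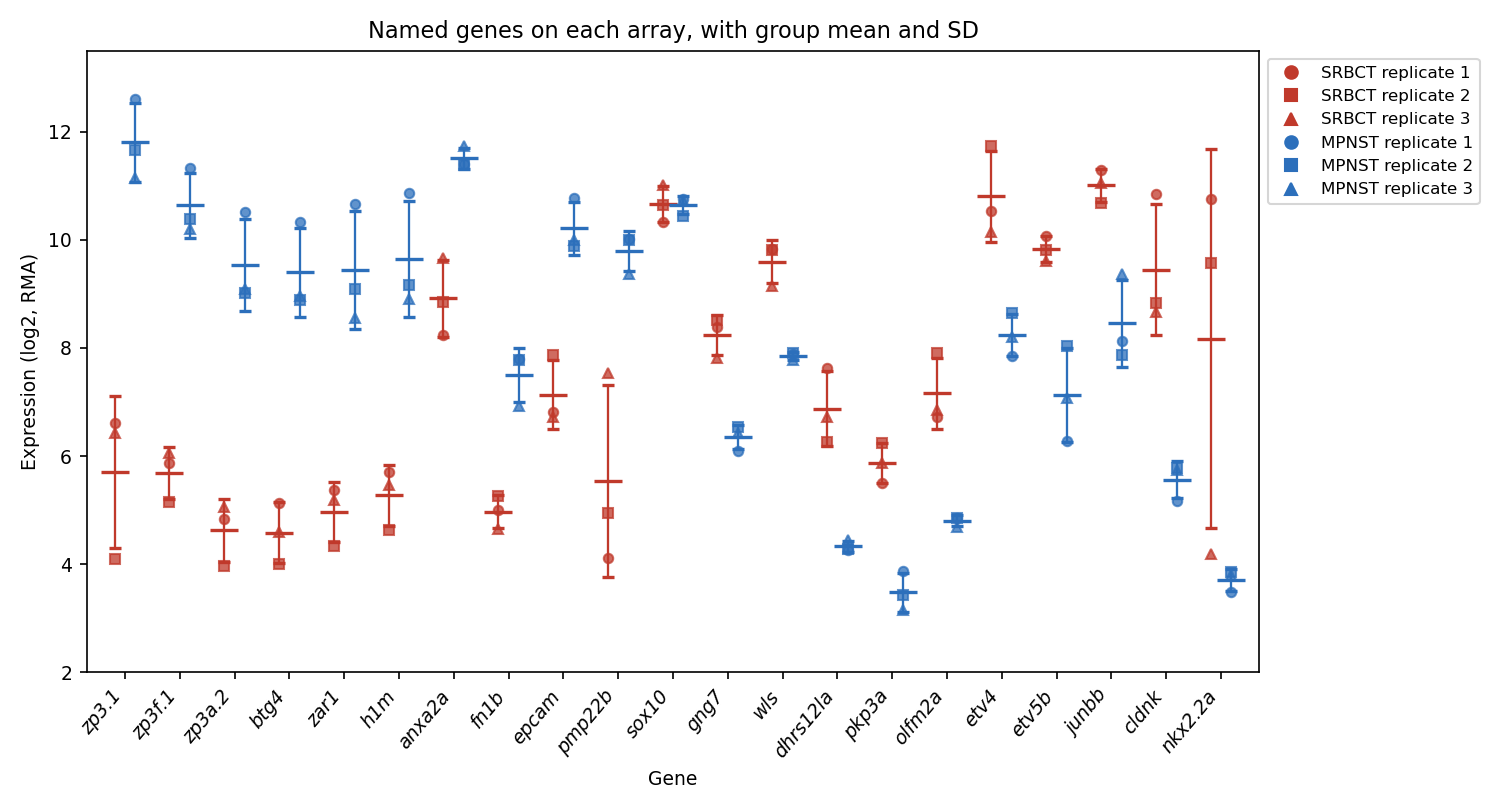
Expression of 21 named genes (x axis) in log2 units (y axis) on each array, with SRBCT in red and MPNST in blue. Horizontal bars are group means and error bars are SD over 3 arrays. The egg coat and maternal genes at the left are at 8.56 or above on each MPNST array and at 6.61 or below on each SRBCT array, and nkx2.2a is at 10.76 and 9.58 on SRBCT 1 and 2 but at 4.18 on SRBCT 3.

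The transgene itself was not measured, because the array's probe sets are for zebrafish transcripts and do not check the human fusion. The zebrafish orthologs of the fused genes did not pass the threshold. fli1 was at 5.51 ± 0.34 in SRBCT and 4.98 ± 0.14 in MPNST (difference 0.53, adjusted p 0.35), ewsr1a differed by 0.69 (adjusted p 0.49) and ewsr1b by 0.23 (adjusted p 0.6). nkx2.2a, whose human ortholog is a well-known EWS-FLI1 target, differed by 4.46 (SE 1.64, adjusted p 0.296). It was at 10.76 and 9.58 on SRBCT 1 and 2 and at 4.18 on SRBCT 3. Its difference was 6.46 without that array, which passed the threshold. cd99l2, related to the Ewing sarcoma surface marker CD99, differed by 0.87 (adjusted p 0.387), and by 1.33 without SRBCT 3, which passed the threshold (adjusted p 0.035). The p53 gene itself is not represented among the probe sets named here.

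Lists of genes that EWS-FLI1 controls in human Ewing sarcoma were not called as lists over the 6 arrays. Of 31 measured members of the activated list none passed the threshold, the median difference was 0.10 and camera's adjusted p was 0.439. Its smallest p-values belonged to ptpn13 (1.64, adjusted p 0.168) and myca (2.07, adjusted p 0.214). Without SRBCT 3, 2 members rose and 2 fell. In the repressed list 2 of 30 members fell, and 4 when adjusted over the list alone. These were anxa2a, an annexin (-2.59, SE 0.38, adjusted p 0.0487), and the fibronectin gene fn1b (-2.52, SE 0.31, adjusted p 0.0303), while the list's median was -0.08 and its camera adjusted p 0.12. anxa2a passed in 1 of the 6 fits without an array, the one without SRBCT 3, and fn1b in 2. The list's median was -0.56 without SRBCT 3, where 4 members fell and 1 rose, and -0.46 without SRBCT 2, where the list was called (adjusted p 0.0432).

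Genes of fibroblast growth factor and MAPK feedback were shifted up as a list of 24 (median 0.46, 19 members above 0, camera adjusted p 0.00469). The call was lost with an estimated correlation (adjusted p 0.636) and without SRBCT 3 (adjusted p 0.0725). No member passed over all probe sets, and 5 rose when adjusted over the list alone. Without SRBCT 3, 6 members rose over all probe sets. Its leading members were etv5b (2.70, SE 0.45, adjusted p 0.0712), an FGF-induced ETS factor, and the AP-1 gene junbb (2.56, SE 0.43, adjusted p 0.0712), each higher on all 3 SRBCT arrays than on any MPNST array. Among 18 ETS family genes none passed, 2 rose when adjusted over the list alone, and etv4 differed by 2.57 (adjusted p 0.0838). The list's median was 0.20 and its camera adjusted p 0.439.

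Other signalling lists did not pass. The hedgehog pathway (17 members, median 0.24, adjusted p 0.0963) was led by shhb (0.81, adjusted p 0.163). Median differences were 0.08 for the insulin-like growth factor axis (15 members, adjusted p 0.46), where insra differed by 1.99 (adjusted p 0.215), and 0.15 for Wnt and beta-catenin targets (21 members, adjusted p 0.357), where mycb differed by 2.40 (adjusted p 0.224). No member of these 3 lists passed the threshold, in the whole array or within the list alone. Without SRBCT 3, nkx2.2a and shhb of the hedgehog list, insra and mycb rose and the Wnt receptor gene fzd7b fell (-3.66, adjusted p 0.0149). The hedgehog list was called without SRBCT 2 (median 0.34, adjusted p 0.0336).

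Neuronal and neuroendocrine markers were shifted up as a list. Of 55 members 48 had a difference above 0, with a median of 0.50 and a mean of 1.04, and camera's adjusted p was 6.35e-06, or 0.636 with an estimated correlation. None passed singly, and the Notch ligand gene dla differed by 2.40 (SE 0.57, adjusted p 0.156). In the fit without SRBCT 3, 17 of the 55 rose. Brain and glia markers also passed as a list (56 members, median 0.23, adjusted p 0.0135, and 0.636 with an estimated correlation) with no member past the threshold. This call was lost with a second quantile normalization (adjusted p 0.0545), without dim probe sets (0.0648) and with the spike-in level as a covariate, a setting chosen after seeing the data (0.283). The paralogous glutamine synthetase genes moved apart, glula differing by 1.65 (adjusted p 0.109) and glulb by -1.49 (adjusted p 0.105). Of the 56, 9 rose and 1 fell without SRBCT 3.

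Schwann cell and neural crest markers, the lineage of MPNST, were not called as a list (34 members, median 0.34, camera adjusted p 0.235), and no member passed over all probe sets. The neural crest and glial regulator sox10 was at 10.66 ± 0.34 in SRBCT and 10.64 ± 0.17 in MPNST (difference 0.02, adjusted p 0.974). The claudin gene cldnk, expressed by myelinating glia, differed by 3.89 (SE 0.60, adjusted p 0.0575), and pmp22b, encoding a peripheral myelin protein, by -4.26 (SE 0.86, adjusted p 0.111). When adjusted over the list alone 1 gene rose and 1 fell. Without SRBCT 3, 4 members rose, among them sox9b (7.14) and fabp7a (7.57), and 4 fell, among them pmp22b (-5.26) and snai1a (-5.18). The myelin gene mbpa differed by 0.57 (adjusted p 0.563). Pigment cell markers (10 members, median 0.30, adjusted p 0.208) were led by gch2 (2.66, adjusted p 0.298).

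Markers of tissues around a tumour differed between single arrays. Gonad and germ cell markers were shifted down (36 members, median -0.56, mean -1.32, camera adjusted p 6.35e-06, and 0.636 with an estimated correlation). 5 of them fell over all probe sets and 12 when adjusted over the list alone. The count was 0 without SRBCT 1, MPNST 2 or MPNST 3, 2 without SRBCT 2 and 6 without SRBCT 3 or MPNST 1, while the list was called in all 6 fits. Liver markers were shifted down (40 members, median -1.13, adjusted p 0.0458, and 0.791 with an estimated correlation). Their median relative to the 6-array mean was 2.82 on MPNST 1 and between -0.88 and -0.36 on the 5 other arrays. Without MPNST 1 the list's median was 0.22 and it was no longer called (adjusted p 0.083), nor was it without SRBCT 2 or SRBCT 3, the highest adjusted p being 0.309. Intestine and pancreas markers were shifted up (30 members, median 1.23, adjusted p 0.00161, and 0.745 with an estimated correlation). Their relative median was 2.88 on SRBCT 3, and without that array the difference was 0.06 (adjusted p 0.549). Within these lists the liver transferrin gene tfa differed by -3.52 (adjusted p 0.303) and the somatostatin gene sst1.1 by 1.56 (adjusted p 0.0916), and 2 genes of the intestine and pancreas list rose when adjusted over the list alone.

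No blood cell marker gene passed over the 6 arrays, and ptprc passed in 1 of the 6 fits that left out 1 array. Leukocyte markers were shifted down, just past the threshold (46 members, median -0.34, adjusted p 0.0489, and 0.636 with an estimated correlation), with the cathepsin gene ctss2.1 at -2.23 (adjusted p 0.185) and ptprc, the leukocyte common antigen CD45, at -1.47 (adjusted p 0.252). This call was lost without SRBCT 3, MPNST 1 or MPNST 3, the highest adjusted p being 0.223. Erythroid markers did not pass (20 members, median -0.19, adjusted p 0.0963), but did without MPNST 1 (adjusted p 0.0101), with cyclic loess (0.0485) and with the replicate block (0.0427), and the globin gene hbaa1 differed by -1.45 (adjusted p 0.277).

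Skeletal muscle markers (51 members, median 0.28, adjusted p 0.000432, and 0.564 with an estimated correlation) and retina and lens markers (47 members, median 0.27, adjusted p 0.000249, and 0.44 with an estimated correlation) were shifted up by small amounts with no member past the threshold. Their median levels of 4.18 and 3.91 lay in the dim part of the range, tnnt2a being at 3.81 ± 0.16 in SRBCT and 2.91 ± 0.08 in MPNST. Control probe sets without a target in the sample differed by a median of 0.25 in the same direction, with overlap between the groups. fry, which tests whether a list's genes move on balance one way, called these 2 lists alone (adjusted p 0.0248 for both). Cartilage and bone markers were shifted up (24 members, median 0.45, camera adjusted p 0.00839, and 0.636 with an estimated correlation), and col11a1a differed by 0.99 (adjusted p 0.191). Without SRBCT 3, sox9a, sox9b, col9a3 and col11a1a of this list rose, as did actc1b of the muscle list and gnb1a of the retina and lens list. Without dim probe sets 6 of the 24 remained, with a median of -0.29, and the call was lost (adjusted p 0.977), as it was with the spike-in level as a covariate (0.0835).

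Among epithelial and skin markers (53 members, median 0.33, adjusted p 0.221) the adhesion gene epcam fell (-3.08, SE 0.41, adjusted p 0.0344), pkp3a rose and 51 did not pass. epcam passed in 2 of the 6 fits that left out 1 array. Without SRBCT 3, s100v2, krt8, krt18b, jupa, icn and epcam fell and pkp3a rose. The list was called upward without SRBCT 1 (adjusted p 0.034) and downward without dim probe sets (21 members, median -0.95, adjusted p 0.0171), so its direction is not settled. Adjusted over the list alone, 1 rose and 2 fell. In fibroblast and matrix genes (46 members, median -0.05, adjusted p 0.443) fn1b was the only one to fall, also over the list alone. Without SRBCT 3, timp2a fell too (-2.87) and col11a1a rose (1.19). Endothelial markers (23 members, median 0.18, mean -0.03, adjusted p 0.731) and myogenic progenitor markers (18 members, median 0.11, mean -0.05, adjusted p 0.731) had medians and means of opposite sign and no member that passed. For mrc1a the difference was -0.87 (adjusted p 0.219) and for six4b 0.53 (adjusted p 0.409). Without SRBCT 3, the endothelial genes aqp1a.1 and cav1 and the myogenic gene mef2aa fell, and the endothelial gene efnb2a rose.

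Lists of general cell functions did not pass over the 6 arrays, but some did without 1 array. In the cell cycle list (68 members, median 0.25, adjusted p 0.12) birc5b, a survivin gene, fell (-4.03, SE 0.52, adjusted p 0.0314) against the list's direction, also over the list alone. birc5b was at 10.19 on MPNST 1 against 9.12 and 9.35 on MPNST 2 and 3, and whether it belongs with the oocyte transcripts was not tested. It passed in 1 of the 6 fits that left out 1 array, the one without SRBCT 3, and not with cyclic loess or the replicate block. The cell cycle list was called without SRBCT 3 (median 0.49, adjusted p 0.00281, with 5 risen and 1 fallen) and without MPNST 1 (adjusted p 0.0103). Medians were -0.30 for p53 target genes (25 members, adjusted p 0.12), led by pmaip1 (-0.87, adjusted p 0.302), and -0.15 for heat shock proteins and chaperones (38 members, adjusted p 0.455). In the chaperone list ahsa1a rose, and 1 gene rose and 1 fell over the list alone. Hypoxia and glycolysis genes (39 members, median 0.13, adjusted p 0.588), ribosomal proteins (72 members, median 0.07, adjusted p 0.367), oxidative phosphorylation (84 members, median 0.14, adjusted p 0.149) and the proteasome (48 members, median -0.13, adjusted p 0.208) had no gene past the threshold. Oxidative phosphorylation was called without MPNST 2 (adjusted p 0.038) and the proteasome without MPNST 1 (adjusted p 0.0103). The smallest p-values in them were those of bnip3 (1.19, adjusted p 0.124), rpl4 (0.56, adjusted p 0.273), atp5pb (1.08, adjusted p 0.174) and psma5 (-0.76, adjusted p 0.219). Without SRBCT 3, bnip3, egln3 and atp5pb rose, and p4ha1b, psmb13a, psmb12 and the p53 targets pmaip1 and plk2b fell. Of 42 hox genes none passed (median 0.13, mean -0.06, adjusted p 0.731), with hoxa5a at -1.76 (adjusted p 0.292). Without SRBCT 3, 5 hox genes fell, and without SRBCT 2 the list was called upward (median 0.28, adjusted p 0.0466).

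**Figure D3:**
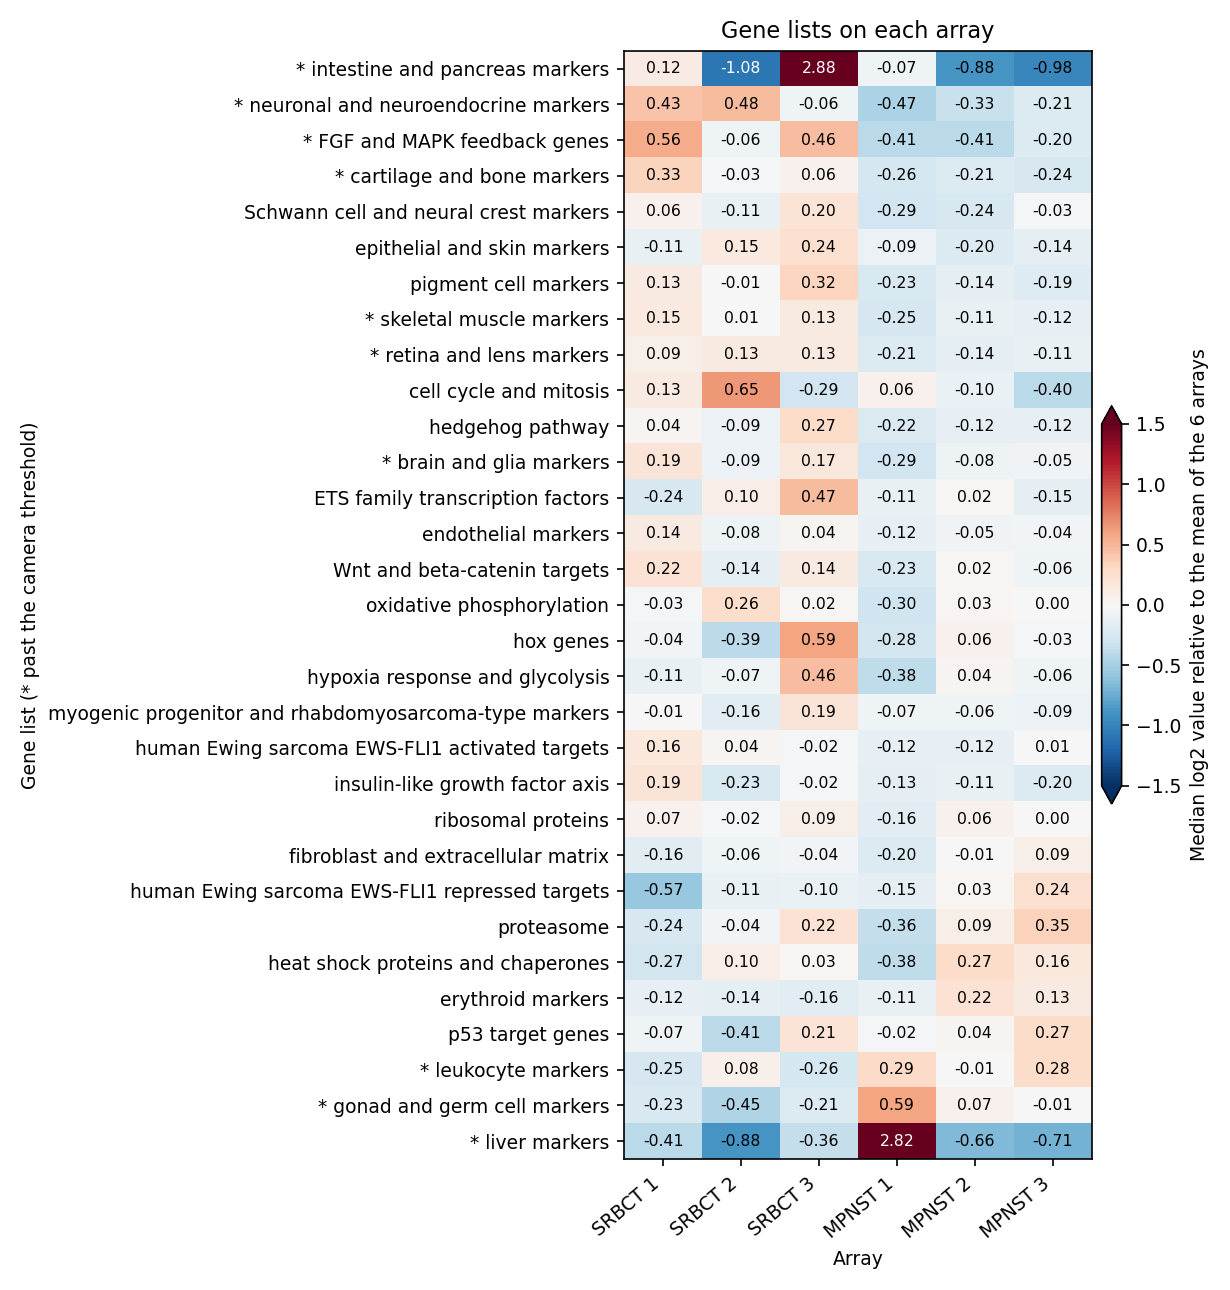
Median log2 value of each of the 31 gene lists (y axis, ordered by difference between groups) on each array (x axis), relative to the mean of the 6 arrays. Red is above and blue below that mean, the scale ends at 1.5 in either direction, and an asterisk marks the 10 lists past camera's threshold. The largest values stand on single arrays, 2.88 for intestine and pancreas markers on SRBCT 3 and 2.82 for liver markers on MPNST 1.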

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

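In this part, the test on vitellogenin and the test of SRBCT 3 as an MPNST like the other 3 were fixed before their values were seen, and the others were chosen after.

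Control probe sets, which are not among the tested probe sets, were higher on average in SRBCT, but the groups overlapped and a difference between them is not shown. The hybridization spike-ins, bacterial transcripts added to every sample, were higher in SRBCT by a mean of 0.94 log2 units over 14 probe sets (8.87 ± 1.07 against 7.93 ± 0.21, SD, n = 3, exact two-sided permutation p 0.4). Control probe sets with no target in the sample were higher by a median of 0.25 over 44 probe sets, and 41 of them had a positive difference (exact two-sided permutation p 0.3). SRBCT 2 did not share these rises, with its spike-ins at 7.70 against 7.79 to 8.18 on the MPNST arrays and its controls without a target at 3.18 against 3.09 to 3.25.

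The oocyte and egg coat transcripts were high on the 3 MPNST arrays. Controls without a target were not lower in SRBCT (median difference 0.25), so a lower array background there is argued against. The median of the 126 lower probe sets, -4.71, is no test of this, because they were selected for their fall. Probes shared between paralogs are not settled. Of the 126, 103 have no name ending that marks shared probes, so marked sharing does not account for most of them. The probe sets that stood for zp3.1 and qdprb.4 do have such an ending. The share of such endings over all probe sets was not compared, and cross-hybridization that the names do not mark was not tested. Ovary tissue in the dissected MPNST samples may account for the pattern. The 11 oocyte members of the gonad list differed by a median of -3.84 (5 past the threshold) and the 9 testis members by 0.05. Ovary tissue would also bring follicle and steroid synthesis genes and germ cell genes of both sexes. By median these moved less (-0.56, 0 of 5 past the threshold, and -0.29, 0 of 11). Differences were below 0 for 3 of the 5 and 9 of the 11. Median levels of the germ cell genes were 5.89, 4.7 and 4.62 on MPNST 1, 2 and 3 and 3.44 to 4.38 on SRBCT. Those of the follicle genes were 5.41, 4.88 and 4.09 against 3.56 to 4.09. Both were highest on MPNST 1, where the oocyte members were highest too. How far ovary tissue would move them was not tested, so the smaller medians cannot decide. A female fish as the source of MPNST 1 was predicted to raise its vitellogenin genes. They were only 0.087 above the SRBCT mean although its liver markers were high. The vitellogenin probe sets were dim on all 6 arrays, at most 5.25, so they may not report the gene well and the test cannot decide. The oocyte members had a median level of 10.34, 8.42 and 7.30 on MPNST 1, 2 and 3 and of 4.42 to 5.13 on the SRBCT arrays. Ovary tissue and expression by the tumour cells stay open, the latter untested.

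SRBCT 3 stood apart from SRBCT 1 and 2. A swap between the groups is argued against, because the highest correlation of an MPNST array with SRBCT 1 or 2 was 0.872 and the lowest between MPNST arrays 0.938. Dilution by gut and pancreas tissue is not settled by the drop in SRBCT 3 among 299 bright probe sets higher in SRBCT 1 and 2. The drop ranged from 0.71 at the 10th percentile to 4.99 at the 90th, a distance of 4.28. Expression of some of these genes in gut or pancreas, or values near the floor, would also spread the drops. An MPNST like the other 3 under a wrong label is argued against over probe sets lower in SRBCT, where SRBCT 3 lay further towards SRBCT 1 and 2 than each left-out MPNST array by at least 0.30 of the distance; over probe sets higher in SRBCT the leads were 0.121, 0.087 and 0.087, with SRBCT 3 at 0.103 to 0.127 of the distance. Over lower probe sets that do not share the oocyte genes' shift on MPNST 1, the leads were 0.072, 0.158 and 0.151, the smallest with MPNST 1 left out, the array by which these probe sets were chosen, so an MPNST without oocyte transcripts cannot be told apart from an SRBCT of another kind, which remains the untested biological explanation.

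The small rise of the skeletal muscle list (median 0.28) and the retina and lens list (median 0.27) in SRBCT may come from a higher array background, since controls without a target were higher by 0.25, though on SRBCT 2 they were not raised while its relative list medians were 0.01 for muscle and 0.13 for retina and lens. After cyclic loess the medians were 0.17 and 0.15 and both lists still passed (adjusted p 0.00883 and 0.00582). With the dimmer probe sets left out, 6 muscle genes remained (median 0.38, adjusted p 0.175) and too few retina and lens genes for a test. Of random lists matched on level, 99.7% and 99.6% had a median at or below the observed ones, around a median of 0.13. Background and expression cannot be told apart here, because nearly all members are dim.

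Of the 10 splits of the 6 arrays into 3 and 3, 1 gave 140 changed probe sets, the real one, and the highest of the others gave 0. For genes the real split gave 77 and the highest other 0. For gene lists the real split gave 10 and the highest other 9, and 1 split reached 10. With 10 splits a share under 0.05 cannot be reached.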

How the results depend on the processing

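Of the settings below, the spike-in level as a covariate and muscle actin were chosen after seeing the data. The 140 changed probe sets, 90% lower in SRBCT, became between 108 and 204 with median centring, a second quantile normalization, cyclic loess, the dimmer probe sets left out, a trended and robust variance or a minimum log2 difference of 1, with 84.8% to 91.7% lower. The higher ones, 14 at first, were 9 with cyclic loess and 31 without dim probe sets. Array weights gave 278 probe sets (83 higher, 195 lower) and 153 genes. The spike-in covariate gave 37 (2 higher, 35 lower) and 16 genes. Without moderation limma called 0 probe sets, 0 of them higher and 0 lower, and 0 genes, with 1864 probe sets at an unadjusted p under 0.05. Leaving out 1 array gave 26 to 1140 probe sets (2 to 569 higher, 23 to 571 lower), 12 to 630 genes and 7 to 12 lists.

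With the replicate block 88 probe sets were changed (4 higher, 84 lower) and 44 genes. Deviations of same-numbered arrays correlated at 0.063, 0.07 and -0.046, so the numbers do not pair the samples.

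Of the 10 called lists 5 were called without dim probe sets, where the epithelial and skin list made 6, and the counts were 0 with an estimated correlation and 2 with fry. Calls were also lost by leukocyte and liver markers with cyclic loess (adjusted p 0.058 for both) and array weights (0.0681 and 0.718), by leukocyte markers with the mean of a gene's probe sets (0.0503), and by brain and glia markers with a second quantile normalization (0.0545) and without dim probe sets (0.0648). Calls were gained by the cell cycle list with a second quantile normalization (0.0288) and cyclic loess (0.0442), oxidative phosphorylation with a second quantile normalization (0.0231), the proteasome with array weights (0.0122), and erythroid markers with cyclic loess (0.0485) and the replicate block (0.0427). With the spike-in covariate 7 lists passed, and the calls of FGF and MAPK feedback genes (0.205), cartilage and bone (0.0835), leukocyte (0.34), liver (0.062), intestine and pancreas (0.332) and brain and glia markers (0.283) were lost, while cell cycle (0.00217), oxidative phosphorylation (0.0349) and epithelial and skin (0.0273) were gained. The epithelial and skin list turned from a median of 0.33 to -0.95 without dim probe sets (adjusted p 0.0171), and the liver list from -1.13 to 0.22 without MPNST 1 (adjusted p 0.083), its lowest value being -1.62 without MPNST 3. The cartilage and bone list's median turned from 0.45 to -0.29 without dim probe sets and its call was lost (adjusted p 0.977). Medians of lists not called also turned without dim probe sets: hox genes to -1.66 (7 genes, adjusted p 0.0694), endothelial to -1.07, myogenic to -0.95, pigment to -0.64 and ETS genes to -0.33. The GAPDH difference of -0.42 turned to 1.59 with muscle actin. The causes of these shifts were not tested. Of single named genes, 139 values in planned settings lost the threshold, 37 gained it and 1081 stayed on their side. An alternative for linear values was not run, since the values are logarithms. Dim probe sets limit what can be seen: RMA compresses them.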

Other observations

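The tests in this part were chosen after the values were seen, and so were the genes named.

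Several neural progenitor and glial genes were high on SRBCT 1 and 2 and low on SRBCT 3. olig2, a factor of oligodendrocyte precursors, was at 10.38 and 11.03 on SRBCT 1 and 2, at 3.15 on SRBCT 3 and at 3.19 or below on the MPNST arrays. The same held for sox3 (10.20 and 10.85 against 3.13), the glutamate transporter gene slc1a2b (11.53 and 11.13 against 4.76), sox9b (11.62 and 11.60 against 5.19) and the neuronal genes elavl3 (8.50 and 8.80 against 4.13) and sypa (8.46 and 8.96 against 3.24). In the fit without SRBCT 3, limma gave an adjusted p of 0.00099 for each of these 6. The radial glial gene fabp7a was at 11.64 and 12.28 against 6.67. gfap did not follow, at 4.41 and 3.52 on SRBCT 1 and 2 (difference without SRBCT 3 0.61, adjusted p 0.352). sox2 followed in part, at 10.71 and 10.66 on SRBCT 1 and 2 and at 7.05 on SRBCT 3. It was at 4.27, 3.97 and 7.90 on MPNST 1, 2 and 3 (adjusted p 0.0667 without SRBCT 3). Of the 56 brain and glia markers 9 rose and 1 fell in that fit. 283 genes rose and 347 fell in that fit.

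On SRBCT 3 some neural crest genes were close to MPNST levels. foxd3 was at 9.60 there, 9.67 to 10.29 on the MPNST arrays and 6.60 and 5.30 on SRBCT 1 and 2. snai1a was at 9.18 against 3.74 and 5.05, and dlx5a at 11.92 against 6.09 and 5.06. The hox gene hoxd9a was at 9.39 against 3.68 and 2.82, with 8.53 at most on the MPNST arrays. The genes with which SRBCT 3 sided with the other SRBCT arrays included etv4 (10.14 against 10.53 and 11.74, with MPNST at 8.64 or below), junbb (11.05) and cldnk (8.67). Of digestive enzyme transcripts, ctrb.1 was at 12.21 and prss1 at 11.99 on SRBCT 3, at 8.71 and 8.79 on MPNST 1, at 6.81 and 7.56 on SRBCT 1 and at 5.18 or below on the 3 other arrays. fabp6, an ileal bile acid-binding protein gene, was at 11.28 on SRBCT 1 and 11.10 on SRBCT 3 and at 3.58 on SRBCT 2.

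Liver transcripts stood out on MPNST 1, where fgg, serpina1l and apoa2 were at 11.80, 12.06 and 12.68, against 5.91 or below on each other array. The oocyte genes of the gonad list also had their highest median level on that array. The median of their differences from the mean of MPNST 2 and 3 was 1.84, from -0.03 to 2.73 over the 11 genes.

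Some genes that are not known for a role in oocytes fell in SRBCT too. anxa5b, an annexin gene, differed by -4.06 (adjusted p 0.00555), s100a1 by -3.94 (adjusted p 0.0108) and the fibronectin receptor gene itga5 by -1.64 (adjusted p 0.0321). On MPNST 1, itga5 was at 6.42 against 6.52 and 6.97 on MPNST 2 and 3, anxa5b at 10.95 against 10.69 and 10.61, and s100a1 at 7.96 against 7.58 and 6.69. For contrast, the oocyte gene gdf3 was at 9.53 on MPNST 1 against 7.72 and 7.96 on MPNST 2 and 3. The oocyte gene cpeb1b was at 9.46 against 7.78 and 7.12.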
